A study of Mus musculus with 36 samples.

How the data were processed

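Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on the dorsal hippocampus of male mice for 2 histone marks, acetylation of histone H3 at lysine 9 (H3K9ac) and at lysine 27 (H3K27ac), together with input chromatin. Per the labels, mice carried a control viral vector or a vector with a short hairpin RNA against Acss2, and were untreated or were given ethanol by intraperitoneal injection at 2 g per kg as a 20% solution. The 36 samples form 12 groups of 3 replicates, of which 24 samples are ChIP libraries and 12 are inputs. Groups were taken from the sample labels.

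The authors deposited peak lists, 1 for each mark and condition, which makes 8 lists. The labels of the 3 replicates of a group name the same list, so no value per replicate enters any comparison, and how replicates were pooled is not given in the sources used here. Per the labels, peaks were called for ChIP against input and kept at a false discovery rate of 0.001. The submitters' processing notes name bcl2fastq, STAR 2.5.2a, bedtools, MACS2 and the GRCm38 (mm10) mouse genome, without saying which step used which tool. Each deposited list has 6 columns and no header, with the start and end of each peak and 1 score. The score in the deposited lists is read as the −log10 of a q-value, since it never fell below the −log10 of the false discovery rate and took discrete steps that widen upwards. It is the authors' value, it grows with sequencing depth, and it was used only to rank or filter peaks within a list, with the median-score alternative described below as the one setting that applied a common score to both lists. The number of reads behind each list is not given in the sources used here, so the depth is unknown, and a list from more reads can hold more peaks with no change in acetylation.

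A gene table of the same genome build supplied gene names and the lower and upper coordinate of each gene, and 21887 protein-coding genes on the assembled chromosomes were used. The table gives no strand, exons or untranslated regions, so the planned windows around transcription start sites were replaced by windows around both gene ends. A gene was counted as having a peak when a peak overlapped the 1.0 kb on either side of either gene end. Upper and lower ends below are by coordinate, and either may be the promoter. Peaks were placed by their midpoint at a gene end, inside a gene or outside genes. Unless stated otherwise, peaks off the assembled chromosomes (19 autosomes, X and Y) were left out.

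For each mark, 4 contrasts were made: ethanol against untreated in control vector, ethanol against untreated in the knockdown, and knockdown against control vector in untreated and in ethanol-treated mice. A peak of the first list with no overlapping base in the second was called gained, and a peak of the second with none in the first was called lost. Shares are given with 95% Wilson intervals, which cover counting error only and neither the spread between mice nor differences in depth. With 1 list per group there is no test of a difference between conditions, and no p-value is given. Contrasts that use the same list share that list's chance values, and lists of both marks may have been called against shared inputs. Peaks of the 4 lists of a mark that overlapped or touched were merged into regions, which were counted by the lists that hold them. Random placements of peaks (100, bedtools shuffle with fixed seeds) gave the overlap to be had by chance.

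Before the data were examined, 22 gene lists were fixed, together with the contrasts, the rule for named genes and all alternatives other than those stated to be later. The lists cover ethanol and acetate metabolism, histone acetylation writers, erasers and readers, immediate early genes, learning and memory signalling, glutamate receptors and postsynaptic density, GABA signalling, presynaptic release, voltage-gated ion channels, glucocorticoid and stress response, heat shock and protein folding, cholesterol and fatty acid synthesis, oxidative stress response, and interferon and antiviral response. They also cover markers of excitatory neurons, inhibitory neurons, astrocytes, the oligodendrocyte lineage, microglia and macrophages, endothelial and mural cells, a set of ependymal, choroid plexus and neighbouring brain region markers, housekeeping genes and genes of other tissues. For each list, covered bases are the bases inside peaks within 2.0 kb of the gene ends. The mean change in covered bases of a list was placed as a percentile among 10000 random lists of the same size, drawn from protein-coding genes matched on covered bases in 10 bins. A list below percentile 2.5 is called low and one as far from the top high, both outside the middle 95% of random lists. The percentile removes the change shared by all genes with as much coverage. It describes these lists and is not a p-value, and 8.8 of the 176 percentiles would lie outside the middle 95% of random lists by chance if lists were independent.

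Named genes were Acss2, and for each mark and contrast the 6 gained and 6 lost genes with the highest peak score in the list that holds the peak, among genes with no peak within 2.5 kb of an end in the other list. Predicted genes were skipped. Also named were up to 4 members of each gene list that gained or lost a peak, and genes with an end in the 5 widest regions of each mark. Members whose covered bases are given without a gained or lost peak were chosen after their values were seen.

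Alternatives for peaks were an overlap of at least 50% of the peak, a peak within 1.0 kb counted as shared, only peaks scoring at or above the median of the shortest list of the mark, lists of equal length, peaks in the upper part of the scores (above the median of their own list) against all peaks, merging of peaks within 1.0 kb, leaving out peaks under 300 bp, and all sequences. Alternatives for genes were windows of 500 bp and 2.5 kb, all annotated genes and lists of equal length. After the data had been seen, 4 more were added: counting a peak anywhere in the gene, and, for gene lists, 50 matching bins, covered bases over the whole gene, and random lists matched also on the highest peak score. Leaving out replicates was not run, since no value per replicate enters.

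The calculation was checked on simulated data made from the deposited lists. In each of the 8 comparisons 2000 peaks were removed and 1000 were added clear of real peaks, and 100% of both were recovered. A planted list of genes with all peaks near their ends removed lay at percentile 0. Both outcomes follow from how the data were made and only check the code. The simulation held no difference in depth or threshold, so it does not show how the comparison behaves under one. With the real contrasts, between 3.5% and 7.5% of random lists lay outside the 95% range. Calculations used Python 3.11.15, bedtools 2.31.1, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.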

Results

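Peak lists of H3K9ac and H3K27ac, both marks of active promoters and, for H3K27ac, of active enhancers, were compared in the dorsal hippocampus of mice aged 8 weeks. Ethanol is oxidised to acetate, mostly in the liver, and ACSS2 turns acetate into acetyl-CoA, the donor of histone acetylation. The design therefore asks whether ethanol alters histone acetylation in the brain and whether such an alteration needs ACSS2. Each of the 8 lists stands for the 3 replicates of a group, and all values below are counts from these lists. No replicate error can be attached to them, and the depth behind each list is unknown.

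The H3K9ac lists held 38235 peaks in untreated control mice, 31042 in ethanol-treated control mice, 38484 in untreated knockdown mice and 42120 in ethanol-treated knockdown mice. They covered 22.6, 16.1, 21.7 and 24.1 Mb, with median peak widths of 390, 379, 372 and 359 bp. H3K27ac lists were longer, with 89935, 86110, 101690 and 119317 peaks in the same order, covering 40.1, 38.1, 47.8 and 57.4 Mb with median widths of 272, 276, 290 and 294 bp. H3K9ac lay nearer to genes: 44.9%, 55.0%, 45.7% and 42.1% of its peaks were at gene ends in these 4 conditions, against 22.1%, 23.3%, 19.5% and 17.1% of H3K27ac peaks. In ethanol-treated control mice, the list with the fewest H3K9ac peaks, the share at gene ends was the highest (95% Wilson interval 54.5% to 55.6%). The number of H3K9ac peaks at gene ends was similar in the 4 lists, at 17177, 17080, 17569 and 17749. Those inside genes numbered 15899, 10581, 15746 and 18092, so the higher share goes with fewer peaks away from gene ends. Similar counts do not mean the same peaks. With ethanol in control mice 2886 peaks at gene ends were lost and 743 gained, and genes with an end peak went from 12726 to 12070. Peaks with a counterpart in the other list numbered 23719 in the untreated and 27400 in the ethanol list, so peak counts can hide lost sites.

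**Figure D1:**
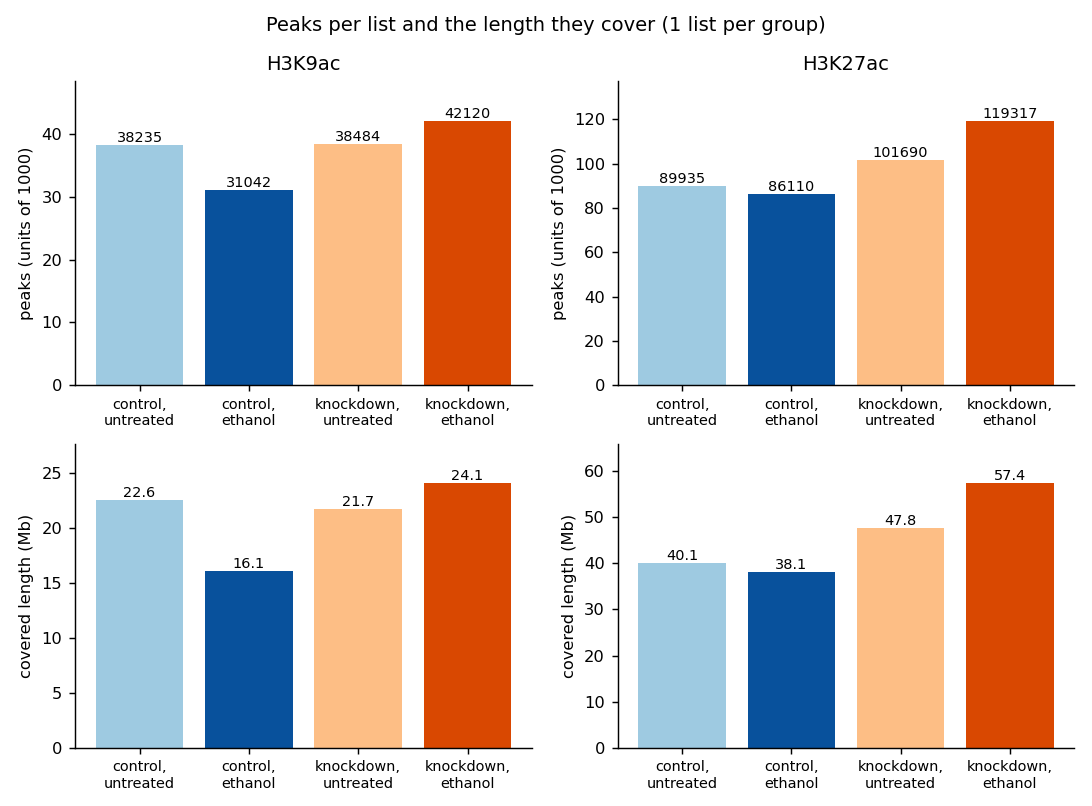
Bars show the number of peaks (upper panels, in units of 1000) and the length they cover (lower panels, Mb) in the 8 lists, with H3K9ac on the left and H3K27ac on the right. H3K9ac covered 16.1 Mb in ethanol-treated control mice and 21.7 to 24.1 Mb in the other lists, and H3K27ac covered 57.4 Mb in ethanol-treated knockdown mice and 38.1 to 47.8 Mb elsewhere.

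Between 85.6% and 91.7% of H3K9ac peaks overlapped an H3K27ac peak of the same condition, against 2.61% to 3.89% for randomly placed peaks. The reverse share was 34.8% in untreated control mice and 27.2% to 28.9% in the other conditions. Merging the 4 lists gave 51682 H3K9ac regions, of which 18999 (36.8%) were present in all conditions, and 149468 H3K27ac regions, of which 40548 (27.1%) were. Regions present throughout were often at gene ends, 63.5% for H3K9ac and 33.5% for H3K27ac. Only 468 H3K9ac regions were found in both ethanol lists and in neither untreated list, and 1120 showed the opposite pattern. The same counts for H3K27ac were 4343 and 2555. The Jaccard index of covered bases between lists of the same mark ran from 0.558 to 0.639 for H3K9ac and from 0.493 to 0.544 for H3K27ac. The highest index for H3K9ac was between untreated control and ethanol-treated knockdown mice (0.639), and for H3K27ac the highest were between lists of the same vector (0.544 in the knockdown and 0.540 in control mice).

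A peak at a gene end was found for 12726, 12070, 12591 and 12859 protein-coding genes with H3K9ac and for 13405, 13439, 13703 and 14030 with H3K27ac. In every list of both marks 11723 genes had such a peak, and in none 7429. Housekeeping genes had a peak at 19 of 20 members in each of the 8 lists, and genes of other tissues at 5 of 24 with H3K9ac and 6 or 7 of 24 with H3K27ac.

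Acss2, on chromosome 2 from 155518043 to 155562743, had peaks at its lower end in all 8 lists. The H3K9ac-covered bases near its ends were 1582 in untreated control mice, 981 in ethanol-treated control mice, 996 in untreated knockdown mice and 1156 in ethanol-treated knockdown mice. H3K27ac covered 1389, 1619, 1614 and 1634 bases. An H3K27ac peak at its upper end (155561845 to 155562270), next to Gss, was present in ethanol-treated knockdown mice alone. This peak was weak, with a score of 3.90 in a list with a minimum of 3.01 and a median of 6.77, and that list is the longest. A short hairpin RNA acts on the messenger RNA, so these values do not check the knockdown.

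**Figure D2:**
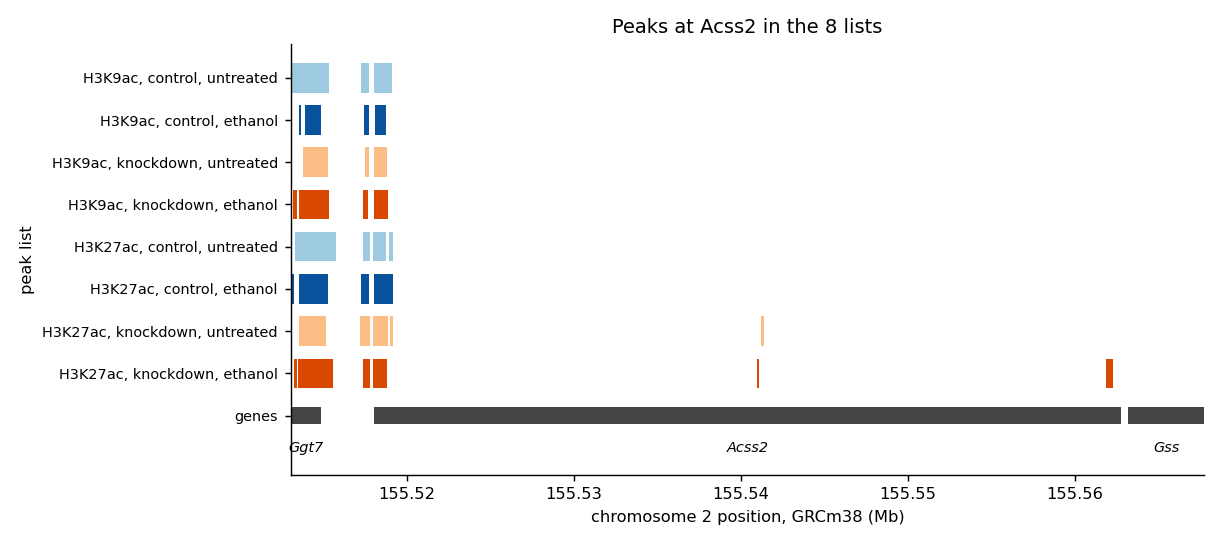
Peaks of the 8 lists (coloured blocks, 1 line per list) along chromosome 2 around Acss2, with the genes Ggt7, Acss2 and Gss as grey bars; the horizontal axis is the GRCm38 position in Mb. All lists have peaks at the lower end of Acss2 (155518043), and the peak from 155561845 to 155562270 is in 1 list.

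The first comparison asked what ethanol does with the control vector. Excitatory neuron and presynaptic genes carried less H3K9ac in the list of ethanol-treated mice. Fewer covered bases were common in this list, and 16 of 20 housekeeping genes had fewer. Of 20 excitatory neuron markers, 19 had fewer and none had more, with a mean of 1858 bp untreated and 1213 bp with ethanol, a change of -644 bp against a median of -324 bp in matched random lists. Of 29 presynaptic release genes 28 had fewer, with means of 1689 and 1047 bp, a change of -642 bp against -329 bp. The synaptic vesicle calcium sensor Syt1 went from 2593 to 534 covered bp, the vesicle protein gene Rab3a from 3319 to 1530 bp, and the neuronal transcription factor genes Neurod1 and Tbr1 from 1820 to 1175 bp and from 1062 to 578 bp. Neurod6, a transcription factor of pyramidal neurons, lost its peak.

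Both lists lay at percentile 0 of matched random lists, which share the change of equally covered genes, and stayed below 2.5 under all 5 alternatives. Here and in the other contrasts, none of these alternatives makes depth or peak width equal between lists. Mean H3K9ac peak width was 591 bp in untreated and 519 bp in ethanol-treated control mice. Narrower peaks from a list of lower depth were therefore not tested as a cause. Of 22 gene lists, 7 were low, below percentile 2.5, and none was high. Immediate early genes, which neurons switch on with activity, had a mean of 2168 bp untreated and 1530 bp with ethanol, with 21 of 24 members less covered (percentile 0.04, but 3.45 in a window of 5 kb and 59.5 when the whole gene was counted). Bdnf lost a peak and Egr2 and Nptx2 gained one, the latter with fewer covered bp (255 untreated, 174 with ethanol), and Arc went from 3199 to 2116 bp. Glutamate receptor and postsynaptic density genes lay at 1.16 (4.41 with lists of equal length), with Grik2 losing its peak. Inhibitory neuron markers lay at 0.77, but 17 of 20 had a peak in neither list, 3 were less covered and 1 more, and the largest change was at Cck, which lost its peak (1938 to 486 bp). The list of ependymal, choroid plexus and neighbouring region markers lay at 0.48, with Fezf2, Adora2a and Kl losing a peak and Lef1 gaining one. With random lists matched on peak score too, the glutamate receptor, inhibitory neuron and ependymal lists moved to 12.6, 7.37 and 3.48.

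Glial lists differed from each other. Astrocyte markers had a mean of 893 H3K9ac-covered bp untreated and 524 bp with ethanol. The gap junction gene Gja1, the intermediate filament gene Gfap and Aldh1l1 lost a peak. The list lay at percentile 0.94, at 2.86 when the whole gene was counted and at 11.2 when matched on peak score. For H3K27ac it lay at 1.865 (6.68 and 10.5 in wider windows), with Acsbg1 losing a peak and Gja1 gaining one. Oligodendrocyte lineage markers went the other way for H3K27ac, with means of 1184 bp untreated and 1444 bp with ethanol, percentile 100, which stayed high under all 5 alternatives. Sox10, the lineage transcription factor, went from 3060 to 4211 bp, the myelin gene Mag from 1962 to 2701 bp, and Cspg4 and Ermn gained a peak while Opalin lost one. For H3K9ac this list lay at 23.1, and Cspg4 gained a peak while its covered bases went from 434 to 139 bp. Excitatory neuron and presynaptic genes were also low for H3K27ac, at percentiles 0.25 and 0.65, the latter 5.32 in a window of 5 kb and 5.71 when the whole gene was counted.

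Across the genome 14516 H3K9ac peaks (38.0%, interval 37.5% to 38.5%) of untreated control mice had no counterpart with ethanol, and 3642 peaks of the ethanol list (11.7%, 11.4% to 12.1%) were gained. Here and below, a lost share is of the list that is compared against, and a gained share is of the list that holds the gained peaks. Only 8.22% of the lost peaks scored above the median of their list. Lost peaks lay at gene ends in 19.9% of cases. H3K27ac was nearer to balance, with 31044 lost (34.5%, 34.2% to 34.8%) and 26238 gained (30.5%, 30.2% to 30.8%). Among peaks at or above a common score, 14285 H3K27ac peaks were gained and 9465 lost, which turns this balance around. That cut was the median of the ethanol list, 6.96, just above the untreated median of 6.88. It kept 46745 ethanol and 40738 untreated peaks, so the ethanol list became the longer one. In all other alternatives more peaks were lost than gained. The change in peak number was -18.8% for H3K9ac and -4.25% for H3K27ac, with no replicate check of either.

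At gene ends, H3K9ac was lost at 789 genes and gained at 133. The highest-scoring losses were Ephx2 (soluble epoxide hydrolase, chromosome 14, peak 66124065 to 66124494), N6amt1, Nuak2, Fam122b, and Il27ra and Rln3, which share a peak on chromosome 8 (84042198 to 84042646). All of these had a peak in both knockdown lists and H3K27ac in all 4 conditions. The gains were Psd4 (chromosome 2, 24367502 to 24367717), Zim1, Plaat5, Ticrr, Wnt6 and Agmo, with widths of 173 to 265 bp. Their score percentiles in the ethanol list ran from 60.9 at Psd4 to 43.8 at Agmo. Here and below, highest-scoring is a rank among gained or lost genes only, and such peaks can lie mid-list. H3K27ac was gained at 376 genes and lost at 342. Its highest-scoring gains were a peak shared by Aire and Dnmt3l (chromosome 10, 78043255 to 78043725), Cyp4f39, Nectin1, Utf1 and H2-Q4, and its losses were Ube2t, Tdg-ps, Fndc9, Mas1, Mtnr1a and Clspn, all 6 of which had a peak in both knockdown lists.

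The second comparison asked what ethanol does when ACSS2 is knocked down. Here excitatory neuron and presynaptic genes carried more H3K9ac with ethanol. The ethanol list covered 10.8% more H3K9ac bases, which by itself favours more covered members. Excitatory neuron markers had means of 1911 bp untreated and 2240 bp with ethanol, with 16 of 20 more covered and 3 less, and presynaptic release genes 1516 and 1803 bp, with 24 of 29 more covered. Tbr1 went from 1690 to 2389 bp, Camk2a, a kinase of the postsynaptic density, from 1299 to 2177 bp, and Sv2b, a vesicle protein gene, from 199 to 1076 bp. These lists lay at percentiles 99.88 and 99.97, and stayed high under all 5 alternatives. Inhibitory neuron markers (26.6) and learning and memory genes (37.6) did not stand out.

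Astrocyte markers had means of 825 and 1038 H3K9ac-covered bp (percentile 99.01, 96.99 with lists of equal length and 95.2 when matched on peak score) and 1361 and 1731 H3K27ac-covered bp (99.72, 85.1 when the whole gene was counted). Ntsr2 gained an H3K9ac peak, and Gja1 and Acsbg1 gained an H3K27ac peak. Glucocorticoid and stress response genes lay at 98.82 for H3K9ac (96.4 with lists of equal length and 95.8 when matched on peak score), with Crh, the stress hormone gene, gaining a peak. Ethanol and acetate metabolism genes lay at percentile 0.21 for H3K27ac, with a mean of 1180 bp untreated and 1148 bp with ethanol, 10 members more covered and 10 less, and moved to 8.26 in a window of 5 kb and 2.65 when the whole gene was counted. Adh7, an alcohol dehydrogenase, gained a peak of both marks with ethanol in the knockdown and one of H3K27ac in control mice. Aldh1a1 gained an H3K27ac peak in the knockdown, and Acss3, a mitochondrial relative of ACSS2, lost an H3K9ac peak. Sox10, Ermn, Mag and Mog, all of the oligodendrocyte lineage, gained an H3K9ac peak (list percentile 94.1).

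Of H3K9ac peaks in ethanol-treated knockdown mice, 13290 (31.6%, interval 31.1% to 32.0%) were gained, and of those in untreated knockdown mice 8204 (21.3%, 20.9% to 21.7%) were lost. H3K27ac gained 46092 (38.6%, 38.4% to 38.9%) and lost 24230 (23.8%, 23.6% to 24.1%). The change in peak number was 9.45% for H3K9ac and 17.3% for H3K27ac, with no replicate check.

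H3K9ac was gained at 519 gene ends and lost at 251. The highest-scoring gains were Tshz2 (chromosome 2, 169633365 to 169633943), Adh7, Ankrd29, Fam167a, Barx2 and Spi1, the microglial and macrophage transcription factor, and each of these also had a peak in untreated control mice. The losses were Acvrl1, Ect2, Derl3, Wdr66, Itih5 and Mc5r. H3K27ac was gained at 526 and lost at 199 gene ends, with the highest-scoring gains at C1ra, Eif2s3y, Plekhn1, Rasef, Adamtsl3 and Klhdc1, and losses at BC053393, Casr, Txlnb, Rsph14, Fam205a1 and Etv3l. Rasef had an H3K27ac peak in this list alone.

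**Figure D3:**
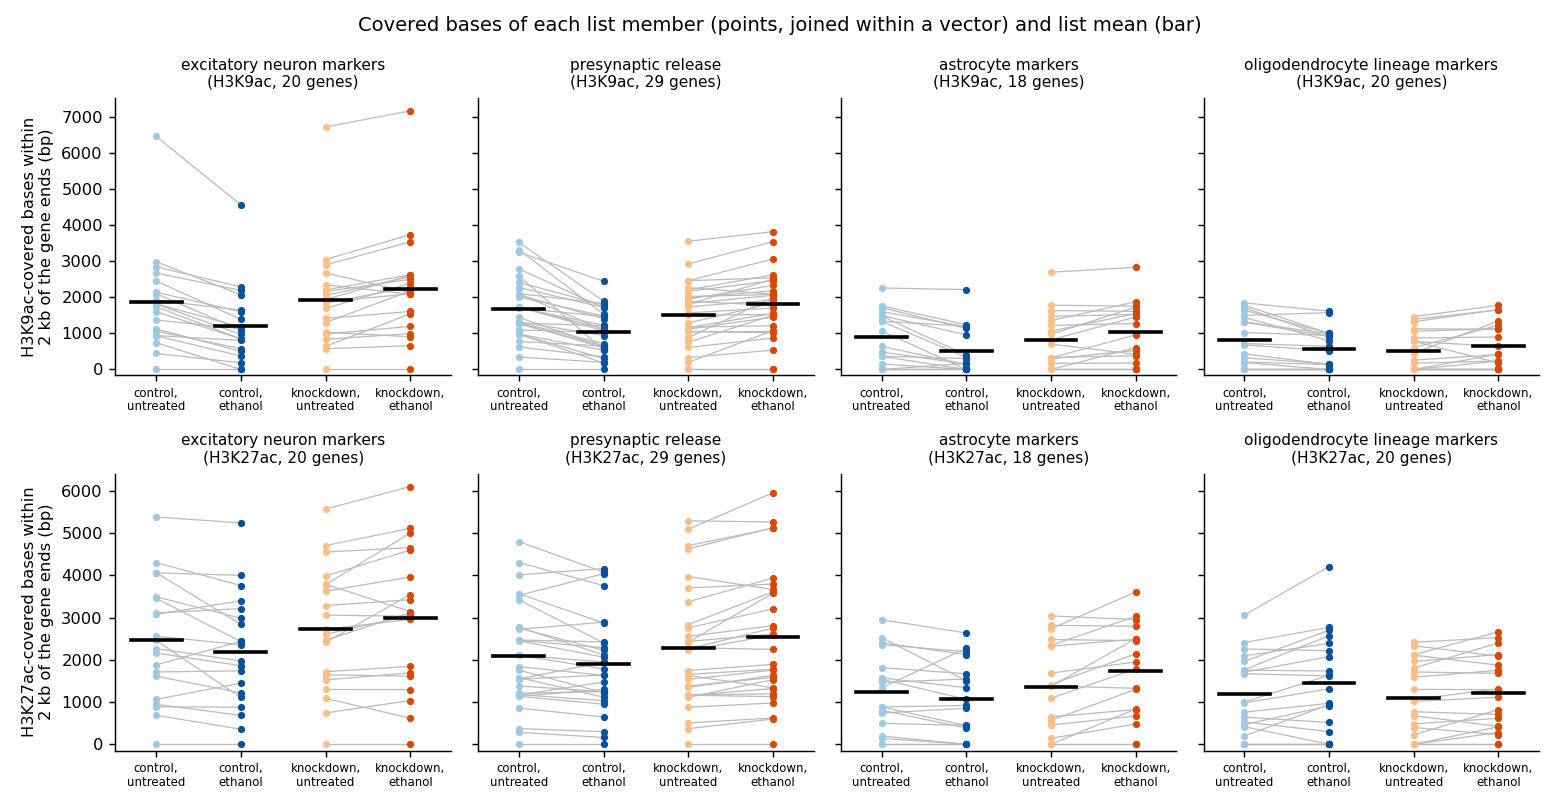
Points show the covered bases (vertical axis, bp within 2.0 kb of the gene ends) of each member of 4 gene lists in the 4 conditions, joined within a vector, with list means as black bars, H3K9ac above and H3K27ac below. Mean H3K9ac over excitatory neuron markers was 1858, 1213, 1911 and 2240 bp from left to right, and mean H3K27ac over oligodendrocyte lineage markers was 1184, 1444, 1099 and 1216 bp.

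The change with ethanol was then followed from control vector to knockdown. Of the 789 genes that lost an H3K9ac end peak in control mice, 574 (72.8%) had one in ethanol-treated knockdown mice and 495 (62.7%) in untreated knockdown mice. A loss in control mice met a gain in the knockdown at 155 genes, against 30.7 for independent lists, and a loss in both at 76, against 14.9. A gain in both was found at 29 genes, against 5.18. All 4 overlaps of H3K9ac lay above these values, the 4th being a gain in control mice with a loss in the knockdown at 11 genes, against 2.51. The values for independent lists count all 13322 genes with an H3K9ac end peak in any list. Of these, 11758 had one in all 4 lists and could not change. The values are therefore too low for genes that could change, and the overlaps do not show a link between the vectors. Of H3K9ac peaks gained with ethanol in control mice, 43.2% (41.6% to 44.8%) were found in ethanol-treated and 35.0% (33.4% to 36.5%) in untreated knockdown mice. Peaks in both control lists were found there in 95.5% and 93.0% of cases, and those lost with ethanol in 50.0% and 40.5%. The H3K27ac shares of gained peaks were 55.0% and 43.8%, of kept peaks 92.9% and 89.5%, and of lost peaks 56.7% and 45.1%. In each class the longer, ethanol-treated knockdown list held more of the peaks.

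The third comparison asked what the knockdown does without ethanol. Oligodendrocyte lineage genes carried less H3K9ac in the knockdown, with a mean of 807 bp with control vector and 514 bp with the knockdown. Sox10 went from 1779 to 451 bp, the myelin gene regulator Myrf from 1320 to 605 bp, and Sox10, Mag and Mog lost a peak. Cspg4 gained one, but its covered bases went from 434 to 174 bp. The list lay at percentile 0 under the chosen settings and all 5 alternatives. For H3K27ac its means were 1184 and 1099 bp (percentile 0.06, 3.34 when the whole gene was counted), with losses at Opalin and Gpr17 and gains at Cspg4 and Ermn. A different share of oligodendrocytes in the tissue was not tested for this list, here or in the other contrasts.

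Interferon and antiviral genes carried more H3K27ac in the knockdown. Of 22 measured members, 17 had more covered bases and 1 had fewer, with means of 616 and 899 bp, at percentile 100 and high under all 5 alternatives. The knockdown list covered 19.1% more H3K27ac bases, which by itself favours more covered members. Irf7, a regulator of interferon genes, went from 384 to 906 bp, Irf9 from 759 to 1289 bp, and Tap1, a peptide transporter of antigen presentation, from 1850 to 2713 bp. Oasl2 gained a peak. Isg15 lost one, although its covered bases went from 825 to 854 bp, and H3K9ac of this list lay at 63.3, with a gain at Oasl2. Genes of GABA signalling lay at 99.61 for H3K27ac (87.2 when the whole gene was counted), with Gabra3 gaining a peak. For H3K9ac, presynaptic release genes lay at 0.96 (13.1 in a window of 5 kb and 9.58 when the whole gene was counted), with Syt2 losing its peak, and microglia and macrophage markers at 1.53, with losses at Spi1 and Cd68. The microglial value lay between 2.46 and 18.9 under the alternatives and is not stable.

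H3K9ac lost 10197 peaks (26.7%, interval 26.2% to 27.1%) and gained 9385 (24.4%, 24.0% to 24.8%), in lists that differ by 0.651% in length. Among peaks above the median score this order turned, with 654 gained and 528 lost. H3K27ac gained 39192 (38.5%, 38.2% to 38.8%) and lost 23455 (26.1%, 25.8% to 26.4%). At gene ends H3K9ac was gained at 296 and lost at 431 genes, and H3K27ac at 536 and 238. The highest-scoring H3K9ac gains were Slc25a21, Tes, Ccrl2, Dpysl3, Ghrh and Mc5r, and the losses Fam167a (chromosome 14, 63436493 to 63436749), Kcnt1, Ptp4a2, Kcnk10, Mamdc2 and Plpp2. All 6 lost genes had a peak again in ethanol-treated knockdown mice. For H3K27ac the gains were BC053393, Pga5, Phox2a, Casr, Psd4 and Txlnb, and the losses Insrr, Kdm5d, Diaph3, Cd247, Chrdl2 and Ifit1bl1.

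The last comparison set knockdown against control vector in ethanol-treated mice, which pairs the H3K9ac list with the most peaks with that with the fewest. The knockdown list covered 49.7% more H3K9ac bases, which by itself favours more covered members in any gene list. Excitatory neuron, presynaptic and astrocyte genes carried more H3K9ac in the knockdown. Excitatory neuron markers had means of 1213 and 2240 bp with 19 of 20 more covered, presynaptic release genes 1047 and 1803 bp with 27 of 29, and astrocyte markers 524 and 1038 bp with 15 of 18. Gja1, Mlc1 and Gfap gained a peak. Their percentiles were 100, 100 and 99.95, and high under all 5 alternatives. Bdnf went from 105 to 796 bp and gained a peak, and Neurod6 went from no covered bases to 1542 bp and gained one.

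Other high lists for H3K9ac were immediate early genes (99.96, but 61.1 when the whole gene was counted, with Egr2 losing a peak), glutamate receptor genes (100, 97.3 when matched on peak score, gains at Grik1 and Grik2), GABA signalling (99.27, 91.4 when matched and 93.7 when the whole gene was counted, gains at Slc12a5 and Gabra3) and the ependymal, choroid plexus and neighbouring region markers (99.41, gains at Kl, Fezf2 and Adora2a). Cholesterol and fatty acid synthesis genes lay low, at 1.31 and below 2.5 under all 5 alternatives, with means of 1209 and 1420 bp. Oligodendrocyte markers lay at 0.98 (no longer low in a window of 5 kb, and 21.9 when the whole gene was counted), with Ermn gaining a peak. For H3K27ac the oligodendrocyte list had means of 1444 bp with control vector and 1216 bp with the knockdown, with a gain at Opalin. It lay at percentile 0 under the chosen settings and all 5 alternatives. Sox10, at 4211 and 2086 bp, made up a large part of the change in the mean.

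High H3K27ac percentiles in this comparison were those of astrocyte (99.99, 77.2 when the whole gene was counted), endothelial and mural cell (99.76), presynaptic (99.76), glutamate receptor (99.76), excitatory neuron (99.75, 92.2 when matched on peak score) and interferon genes (99.32, 97.3 when matched and 96.7 in a window of 5 kb). Among endothelial and mural genes, Emcn, Itm2a and Slco1c1 gained a peak and Erg lost one. Ethanol and acetate metabolism genes lay at 0.21 (12.1 when the whole gene was counted), although 14 members were more covered and 6 less, with gains at Acss3 and Aldh1a1, and glucocorticoid and stress response genes at 1.70 (25.1 when the whole gene was counted), with a gain at Tsc22d3.

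H3K9ac gained 18339 peaks (43.5%, interval 43.1% to 44.0%) and lost 3300 (10.6%, 10.3% to 10.98%), and H3K27ac gained 57730 (48.4%, 48.1% to 48.7%) and lost 16042 (18.6%, 18.4% to 18.9%). H3K9ac was gained at 915 gene ends and lost at 126, and H3K27ac at 732 and 141. The highest-scoring H3K9ac gains were Ccdc114, Trib3, Il27ra and Rln3 with their shared peak, Pcp4 and Trpm2, and the losses Ect2, Cdc6, Insl6, Agmo, Aipl1 and Cyp4f37. Score percentiles of these losses ran from 57.8 at Ect2 to 43.8 at Cyp4f37 in the ethanol-treated control list. For H3K27ac they were Ano9, Mesp1, Eif2s3y, Nr2f2, Rasef and Mtnr1a, and, lost, Sh3tc2, Utf1, Dnaaf6b and Nup62cl with a shared peak, Aspa and Ikzf3. Ect2, which acts in cell division, had 503, 514 and 720 H3K9ac-covered bp in the other 3 conditions and none in ethanol-treated knockdown mice.

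**Figure D4:**
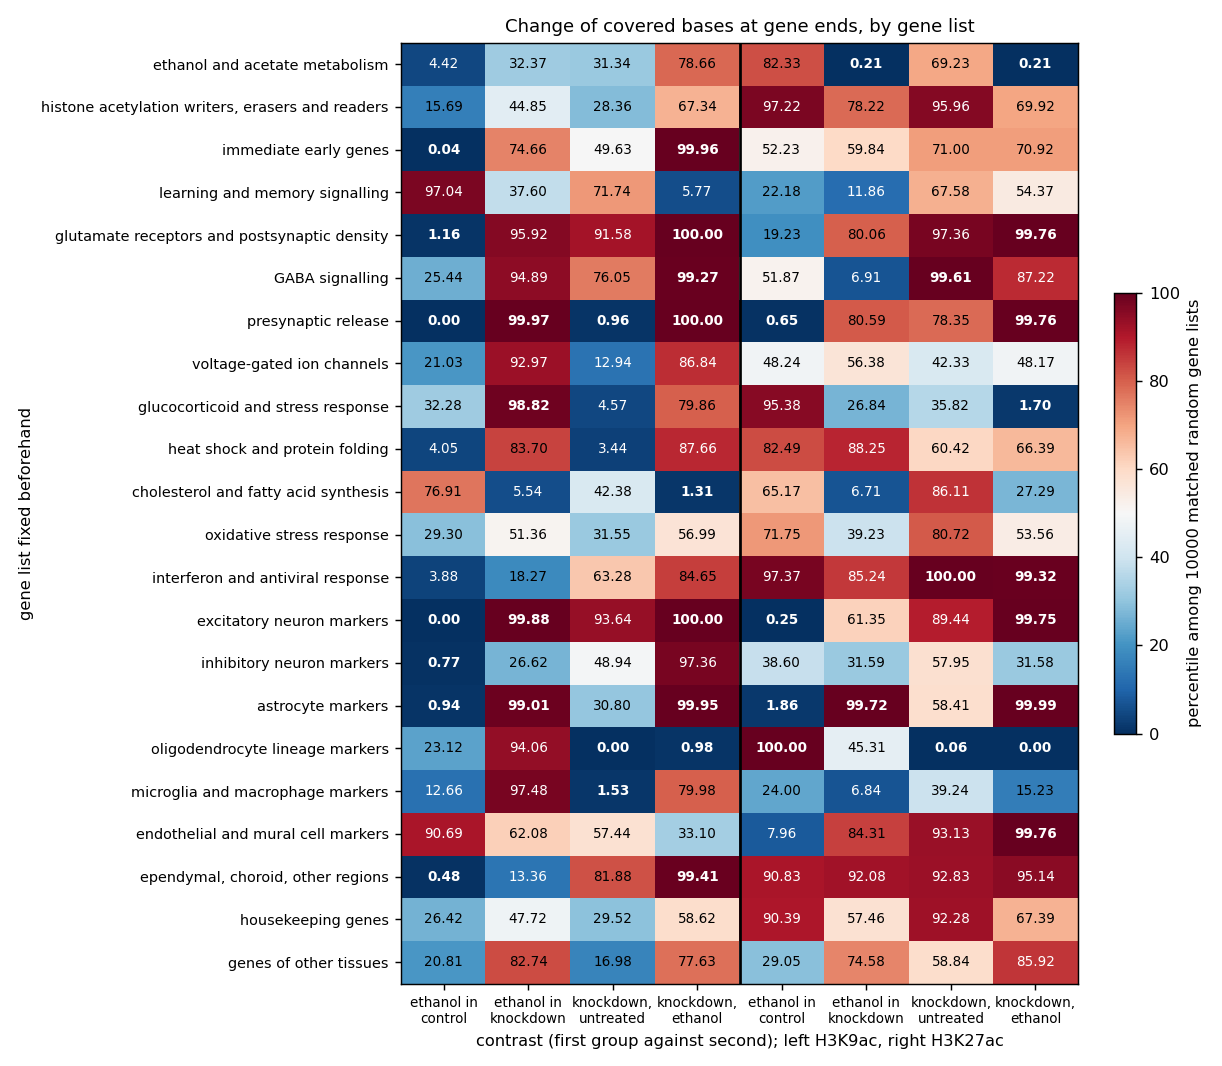
Each cell is the percentile of a gene list's mean change in covered bases among 10000 matched random lists, with gene lists down the vertical axis and contrasts along the horizontal axis, H3K9ac on the left and H3K27ac on the right. Values outside the middle 95% of random lists are in bold, 20 low and 21 high of 176, and 17 of these 41 stayed outside under all 5 alternatives.

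The widest H3K9ac region was on chromosome 19 from 5794676 to 5802630 and held no end of a protein-coding gene, with 7000 to 7641 covered bp in the 4 lists. The next were inside Adcy9 and at Irs2, Nptx1, and Cdk5r1 with Myo1d. The Adcy9 region had 5830 covered bp in untreated and 3575 in ethanol-treated control mice, and 5485 and 6724 in the knockdown. The widest H3K27ac regions were at Ppp1r9b (chromosome 11, 94986925 to 94999690), Dagla, and Camk2a with Arsi, and inside Zbtb16 and Dnal4. Ppp1r9b, Dagla and Camk2a act at synapses.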

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

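The tests of the share of lost peaks above the median score, of lost astrocyte peaks against genes matched on score and both tests of the neuronal genes were chosen only after the results were seen; the tests of loss shared by both marks and of the astrocyte share were set down before.

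Ethanol went with opposite changes in the lists of control and knockdown mice for the values given first, and since each is 1 list per group these differences were not tested. The change in H3K9ac peak number was -18.8% in control mice and 9.45% in the knockdown, and that in covered length -28.7% and 10.8%. For H3K27ac the number changed by -4.25% and 17.3% and the covered length by -4.85% and 20.1%. Genes with an H3K9ac peak at an end numbered 656 fewer in control mice (a change of -656) and 268 more in the knockdown. The percentile of the change in H3K9ac-covered bases was 0 and 99.97 for presynaptic release genes, 0 and 99.88 for excitatory neuron markers and 0.94 and 99.01 for astrocyte markers. For H3K27ac, astrocyte markers lay at 1.865 and 99.72. The H3K27ac values that follow went the same way in both vectors. Genes with an end peak went from 13405 to 13439 in control mice and from 13703 to 14030 in the knockdown. At a common median score, 14285 H3K27ac peaks were gained and 9465 lost in control mice, and 17271 gained and 10970 lost in the knockdown. This agreement depends on the cut, which kept more ethanol than untreated peaks in control mice. Without it the directions were opposite, with 26238 gained and 31044 lost in control mice and 46092 gained and 24230 lost in the knockdown.

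Peaks off the assembled chromosomes, which the comparisons leave out, numbered 196 for H3K27ac in ethanol-treated control mice and 163 in untreated ones, where counting error reaches 190.0. On an unplaced scaffold that list had 34 peaks against 9 in untreated control mice, where counting error reaches 17.1, and 3 and 4 in untreated and ethanol-treated knockdown mice. H3K9ac peaks on the same scaffold numbered 65, 18, 72 and 74 in the 4 conditions.

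The 14516 H3K9ac peaks missing from ethanol-treated control mice could come from a list with fewer reads or a stricter effective threshold, or from a loss of acetylation with ethanol. A threshold would remove weak peaks first, and 8.22% of the lost peaks scored above the median of the untreated list. Weak peaks would also vanish first in an even loss of acetylation, so this value is what both need. If the loss touched both marks, H3K27ac would vanish more often where H3K9ac did. H3K27ac peaks were lost at 17.7% of sites that lost H3K9ac and 3.82% of sites that kept it. Among all H3K27ac peaks of untreated control mice, with or without H3K9ac, 34.5% were lost. At matched H3K27ac score the ratio was 1.47 (95% interval 1.37 to 1.59 over 1000 resamples of single peaks). The interval does not hold the spread between mice or libraries. The ratio lay between the limits of 1.1 and 1.5 set for it, so a shared loss remains undecided. Nor could a higher ratio separate a shared loss of acetylation from weaker detection in both lists, since score was matched only in 10 groups.

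Of the astrocyte markers, 4 lost an H3K9ac peak with ethanol in control mice. A lower share of astrocytes in the tissue could also lower H3K27ac at the list, and its percentile there was 1.865, though 10.5 when the whole gene was counted. A detection threshold could remove these peaks if they were weak, and then other genes with peaks of the same score would lose as many. Of 10000 random draws of 14 genes matched on score, 35.9% lost at least 4 peaks, with a mean of 3.06. Both tests came out as their explanation needs, and neither is preferred. A change of acetylation within astrocytes was not tested.

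Excitatory neuron and presynaptic genes had fewer H3K9ac-covered bases with ethanol in control mice than matched genes. A lower share of neurons alone was taken to raise the markers of other cell types together. The H3K27ac percentiles of oligodendrocyte and astrocyte markers stood 98.135 apart, at 100 and 1.865, so they did not rise together. A rise of oligodendrocytes with fewer neurons and astrocytes would give the same values, so the test cannot decide on the neuron share. H3K27ac of excitatory neuron and presynaptic genes was also low, at 0.25 and 0.65, as a lower neuron share would need. The astrocyte side of the test moved to 10.5 with whole genes, and the H3K9ac percentile of astrocyte markers was 11.2 when matched on peak score. Weaker peaks at these genes would let matched score remove the pattern, and the excitatory neuron percentile was then 0.04. A different share of cell types, a difference between pooled libraries and an ethanol effect on neuronal acetylation all stay open, the last as a hypothesis.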

How the results depend on the processing

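The setting that counts a peak anywhere in a gene, and the settings with 50 matching bins, whole genes or matching on peak score for gene lists, were chosen only after the data were seen. No paired analysis was possible because each group has 1 pooled list with no value per replicate, and for the same reason no replicate was left out. Lists of equal length aside, the side with more peaks, gained or lost, was kept in 54 of 56 comparisons of peaks and in 32 of 32 at gene ends. These settings leave a difference in length between lists, which favours 1 side, so this is weak support. The exceptions were H3K9ac in untreated knockdown against control mice with peaks above the median of their own list, and H3K27ac with ethanol in control mice at a common median score. With lists of equal length the number of gained and lost peaks can differ only through splitting of regions, so balance there says nothing on gain against loss. All 16 counts of peaks stayed within 1.5 times when an overlap of 50% was needed or all sequences were used, as did all 16 counts of genes in windows of 500 bp or 2.5 kb and with the whole gene. Of the 41 gene list percentiles outside the middle 95%, 41 stayed there with 50 bins, 37 with lists of equal length, 33 in wider windows, 30 when matched on peak score and 25 with whole genes, and 17 under all of these. The unknown depth of each list limits every count, since weak peaks appear or vanish with it.

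Counts below are given in the order ethanol in control vector, ethanol in the knockdown, knockdown in untreated and knockdown in ethanol-treated mice. When a peak within 1.0 kb counted as shared, gained and lost H3K9ac peaks were 1533 and 8000, 6770 and 3775, 4553 and 5045 and then 10583 and 1360. For H3K27ac they were 10945 and 13344, 21971 and 8593, 18359 and 8483 and then 32560 and 5630. With only peaks at or above the median score of the shortest list, gained and lost H3K9ac peaks were 656 and 5920, 3382 and 1617, 1663 and 3614 and then 5615 and 647. The H3K27ac counts were 14285 and 9465, 17271 and 10970, 17578 and 7733 and then 20588 and 9157. With peaks above the median of their own list set against all peaks, the H3K9ac counts were 130 and 1193, 1005 and 473, 654 and 528 and then 2132 and 118. Those of H3K27ac were 6189 and 6614, 10107 and 4065, 8275 and 4426 and then 15010 and 3350. After merging peaks within 1.0 kb, H3K9ac gave 2019 and 7004, 6804 and 4487, 5016 and 5393 and then 8784 and 1886. H3K27ac gave 12340 and 13809, 20958 and 11431, 17901 and 10734 and then 25494 and 7481. Without peaks under 300 bp, H3K9ac gave 930 and 6678, 4724 and 2606, 2990 and 4049 and then 7639 and 844. H3K27ac then gave 8726 and 10318, 18967 and 8219, 16216 and 6611 and then 25998 and 4354. Counting a peak within 1.0 kb as shared can only lower these counts, as can keeping only peaks above the median of their own list against all peaks. The cause of the lower counts under the remaining settings was not tested.

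With lists of equal length, gained and lost H3K9ac peaks were 4702 and 8647 with ethanol in control mice and 6987 and 5643 with ethanol in the knockdown. In knockdown against control mice they were 6050 and 6943 untreated, and 8880 and 4597 with ethanol. For H3K27ac they were 28024 and 23861 with ethanol in the knockdown, and 31939 and 22602 in ethanol-treated knockdown against control mice. At gene ends, H3K9ac was then gained at 236 and lost at 593 genes with ethanol in control mice. In ethanol-treated knockdown against control mice H3K9ac was gained at 608 and lost at 271 genes, and H3K27ac at 487 and 257. These counts follow from shortening the longer lists.

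With all annotated genes, more genes enter the count. H3K9ac was then gained and lost at 251 and 1499, 1060 and 508, 630 and 865 and then 1782 and 217 genes, and H3K27ac at 939 and 895, 1473 and 577, 1326 and 647 and then 1947 and 416.

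Of peaks gained with ethanol in control mice, the shares found in ethanol-treated and untreated knockdown mice were 40.7% and 32.9% for H3K9ac and 51.1% and 40.5% for H3K27ac with an overlap of 50%. With lists of equal length they were 35.2% and 31.5%, and 42.1% and 37.6%. For gained peaks above the median score they were 60.8% and 57.7%, and 65.5% and 54.8%. With an overlap of 50%, H3K9ac peaks overlapped H3K27ac in 79.6%, 87.5%, 81.0% and 84.4% of cases in control untreated, control ethanol, knockdown untreated and knockdown ethanol lists, and H3K27ac peaks overlapped H3K9ac in 28.9%, 22.4%, 22.5% and 20.7%. In windows of 2.5 kb the shares at gene ends were 60.6%, 70.1%, 61.2% and 57.4% for H3K9ac and 31.7%, 33.3%, 28.7% and 25.9% for H3K27ac. The stricter overlap and the wider window move these shares by construction. The cause of the higher shares among higher-scoring gained peaks was not tested.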

Other observations

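The gene list tests with whole genes, 50 bins and matched peak score were chosen only after the results were seen.

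Several gene lists stayed within the middle 95% of random lists in every contrast of both marks. Learning and memory signalling genes had an H3K9ac peak at 24 of 28 members in every list, and Mef2c, a neuronal transcription factor gene, gained an H3K27ac peak with ethanol in the knockdown. Their percentiles ran from 5.77 to 97.04. Histone acetylation writers, erasers and readers ran from 15.7 to 97.2, with Hdac6 losing its H3K9ac peak with ethanol in control mice (164 covered bp, and 942 bp in ethanol-treated knockdown mice) and Hdac4 gaining an H3K27ac peak in untreated knockdown mice. Voltage-gated ion channel genes ran from 12.9 to 93.0, with Scn1a losing its H3K9ac peak in the knockdown in both treatments and gaining an H3K27ac peak, and Kcna2 and Cacna1d gaining H3K27ac. Heat shock and protein folding genes ran from 3.44 to 88.2, with Hspb1 losing its H3K9ac peak with ethanol in control mice. Oxidative stress genes ran from 29.3 to 80.7, with Nqo1 losing its H3K9ac peak in the same contrast and Txnrd1 gaining H3K27ac with ethanol in the knockdown. Housekeeping genes ran from 26.4 to 92.3 and genes of other tissues from 17.0 to 85.9, with gains at Ckm and Cela1 and a loss at Myh7 with ethanol in the knockdown, where Cela1 went from 355 to 186 H3K27ac-covered bp.

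Inhibitory neuron markers did not stand out for H3K27ac, with list percentiles of 38.6, 31.6, 57.9 and 31.6 in the 4 contrasts, but single members had a peak in some lists only. Npy, the neuropeptide Y gene, had 304 covered bp in ethanol-treated control mice, 387 bp in untreated knockdown mice and none in the other lists. Dlx5 and Dlx6, transcription factor genes of the interneuron lineage, had a peak in ethanol-treated knockdown mice alone, with 155 and 479 covered bp, the Dlx5 peak being weak (score percentile 0.574 in its list), and Dlx2 in ethanol-treated control mice alone, with 163 bp. Of 20 members 4, 6, 4 and 7 had a peak in the 4 conditions. Camk2a is in both the glutamate receptor and excitatory neuron lists, Slc17a7 in both the presynaptic and excitatory neuron lists, and Gad1, Gad2 and Slc32a1 in both the GABA and inhibitory neuron lists.

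H3K27ac regions found in ethanol-treated knockdown mice alone numbered 31298, with a median width of 188 bp. Of these, 47.7% lay within 5 kb of a region present in all 4 lists, and 17.0% held a peak above the median score of the list. The share within 5 kb was 12.2% for 100 random placements on the same chromosomes, drawn without bedtools.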
